A study of Macaca mulatta with 15 samples.

How the data were processed

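Colon miRNA was measured in 15 rhesus macaques, 10 infected intravenously with 100 TCID50 (50% tissue culture infectious doses) of SIVmac251 and 5 uninfected. Per the labels' protocols, total RNA was extracted with a column kit that keeps small RNA, treated with DNase, and 350 ng were reverse transcribed, preamplified and run on the TaqMan human miRNA array, cards A and B (set version 3.0), on a real-time PCR instrument. These assays are designed for human miRNAs, so a macaque sequence that differs, or a related miRNA, can change a Ct. Each of the 2 cards has 384 wells, which makes 768 wells per animal. The card of each well is taken from the order of the deposited table, in which the same layout of control wells occurs once in each set of 384.

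The deposited values per animal are quantification cycles (Ct), not normalised, with 40 in undetermined wells; per the series' design text the authors used RQ Manager 1.2.2 and DataAssist 3.01 with global normalisation and Benjamini-Hochberg correction. The deposited table of the authors' comparison holds a ratio, the fold change of infected over uninfected animals as 2 to the power of minus the normalised Ct difference, per the file headers. The same deposited table holds a p-value per assay, whose test is not given in the sources used here and whose header does not say whether it is adjusted. All columns of per-animal values were assigned to animals through the labels. The cards give no read counts, and the depth of each animal is the number of assays detected and the Ct of each, with the number of animals limiting the precision. The 4 U6 wells of a card differed by a median SD of 0.113 cycles (card A) and 0.122 (card B) within an animal, which is the well-to-well error. No animals were duplicates of each other, since the SD of the Ct difference between any pair was at least 0.634 cycles.

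Ct values were capped at 35, and an assay was called detected under that value. From each capped Ct the animal's median Ct over the assays under 35 in all 15 animals, both cards together, was subtracted, and the sign was turned so that 1 unit is 1 log2 step; log2 values are thus computed here from the deposited Ct. Assays under 35 in at least 5 animals were tested, which left 441 of 754 (267 on card A and 174 on card B). An undetermined assay has its level set by the ceiling, so its fold is a bound. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

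The comparisons were all infected against uninfected animals, 3 stages against uninfected animals (7 to 10 days with 3 animals, 13 days with 3, 21 to 29 days with 4), the later stages against the first, and a slope per 10 days within the 10 infected animals. The stage contrasts share 1 estimate of spread from all 15 animals. Numbers of detected assays and control RNAs (U6, RNU44, RNU48) were compared with exact two-sided permutation tests over all 3003 splits, and detection per assay with two-sided Fisher's exact tests. The plant negative control was read as background. The design, the naming rule, the lists and the alternatives were fixed before the data were examined, except where a setting is said to be chosen after seeing the data.

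The miRNAs named in the main comparison are up to 12 with the largest change per direction among those past the threshold, filled with the smallest unadjusted p to 10 where fewer passed. In the stage and slope comparisons they are the 5 largest per direction past the threshold, or the 3 with the smallest unadjusted p where none passed. Members of lists past the threshold, up to 4 of the most abundant members per list, and miR-210, miR-190b, miR-155, miR-146a, miR-223, miR-150 and miR-21 were also named. The 15 lists, each with at least 4 tested members, were intestinal epithelium, smooth and striated muscle, fibroblast and connective tissue, nervous system, endothelium, lymphocyte and pan-leukocyte, myeloid, erythroid, interferon- and NF-kB-induced, described as binding HIV-1 or SIV RNA, the miR-17-92 family of clusters, let-7, the DLK1-DIO3 cluster, the C19MC cluster and epithelial passenger strands. Some miRNAs are in more than 1 list. Of 220 distinct names written into the lists, 6 had no assay. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry.

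Names of hairpins and neighbouring genes were checked in the rhesus RefSeq gene table, used for names and neighbours only. The genome build behind the assays is not given in the sources used here, and no coordinates are printed.

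The code was tested on simulated data of 441 assays with 60 changed in each of 20 draws. For all infected against uninfected animals it recovered 49.8% of assays changed by 1 log2 unit and 75.4% of those changed by 2, with 5.99% false among the calls. For 13 days against uninfected animals it recovered 27.3% and 64.8%. The simulated errors were drawn independently for each assay and animal. In the real data many assays moved together in some animals (first principal component 60.3% of the variance). These shares may therefore not hold for the real data.

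Alternatives were a Ct ceiling of 32 or 40, undetermined values as missing, assays detected in all 15 animals or in at least 1, normalisation by the global mean, by each card, by control RNAs, by quantiles or not at all, limma with trend and robust spread, exact permutation and rank-sum tests per assay, and each animal left out in turn. After the data were seen, fits without the 4 infected animals that stood apart on the first principal component, with a term for them, and without them with each card scaled by itself were added. No per-animal value was left out of any comparison other than in these alternatives.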

Results

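MicroRNAs were measured in intact colon tissue from 15 rhesus macaques by quantitative PCR on low density array cards. Of these animals, 10 had been infected intravenously with SIVmac251, a pathogenic strain of simian immunodeficiency virus, and 5 were uninfected. The infected animals were sampled at 7, 8 and 10 days after infection (1 animal each), at 13 days (3 animals), at 21 days (3 animals) and at 29 days (1 animal). Each animal gave 1 sample, so n counts animals. The value per assay is the quantification cycle (Ct), in which 1 cycle is about a 2-fold difference and a higher Ct means less RNA. The question behind the series was which miRNAs change in the colon in the first weeks of infection. Levels below are on a log2 scale relative to the animal's own median of commonly detected miRNAs.

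Of 754 miRNA assays, 340 gave a Ct under 35 in all 15 animals, 232 gave none in any animal and 182 did so in some. The number detected per animal was 421 ± 9.39 (SD, n = 10) in infected and 421 ± 9.22 (SD, n = 5) in uninfected animals, with a range from 408 to 445 (exact two-sided permutation test, p = 1). The median Ct of the commonly detected assays was 23.3 ± 0.494 (SD, n = 10) in infected and 23.7 ± 0.494 (SD, n = 5) in uninfected animals (exact permutation test, p = 0.189). Among the control RNAs, U6 on card A read 13.3 ± 1.17 cycles (SD, n = 10) against 13.6 ± 0.630 (SD, n = 5), with p = 0.671 by exact permutation. Of the 6 control tests, RNU48 on card B had the lowest p, 14.7 ± 0.615 cycles against 15.7 ± 0.852 (n = 10 and 5, exact permutation p = 0.0263, adjusted p = 0.158). No control passed after adjustment over the 6. The plant miRNA ath-miR-159a, which no macaque makes, gave its lowest Ct at 30.7 on card A and 30.8 on card B, so single wells near that Ct can be background. miR-130a-5p and miR-23a-5p were each detected in 9 of 10 infected and 1 of 5 uninfected animals (Fisher's exact test, p = 0.0170, adjusted p = 0.963). miR-654-5p was detected in 4 of 10 against 5 of 5 (Fisher's exact test, p = 0.0440, adjusted p = 0.963). These 3 assays were the ones with an unadjusted p under 0.05, and 0 passed after adjustment.

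4 infected animals, those with label numbers 1 (7 days) and 7, 8 and 9 (21 days), stood apart from the other 11 in the whole profile. The first principal component over the 340 assays detected in every animal placed these 4 between 15.3 and 21.5 and the other 11 at -5.79 or lower. miR-1274b, now regarded as a tRNA fragment, was undetermined in all 4 and read between 11.97 and 14.66 cycles in the other 11. miR-320b was undetermined in the 4 and read between 20.61 and 22.15 cycles in the others. miR-486-5p, a red-cell miRNA, read between 14.60 and 16.26 cycles in the 4 and between 28.08 and 31.80 in the others. In all, 17 assays were detected in each of the other 11 animals and in none of these 4, and 16 of the 17 lay in the last 96 wells of card B. miR-1274b, miR-320b and miR-486-5p were chosen after their values were seen. The labels give no plate, lot or run. All 4 animals are infected, so infection cannot be tested inside the set, and the counts below are also given without them, a setting chosen after seeing the data.

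**Figure D1:**
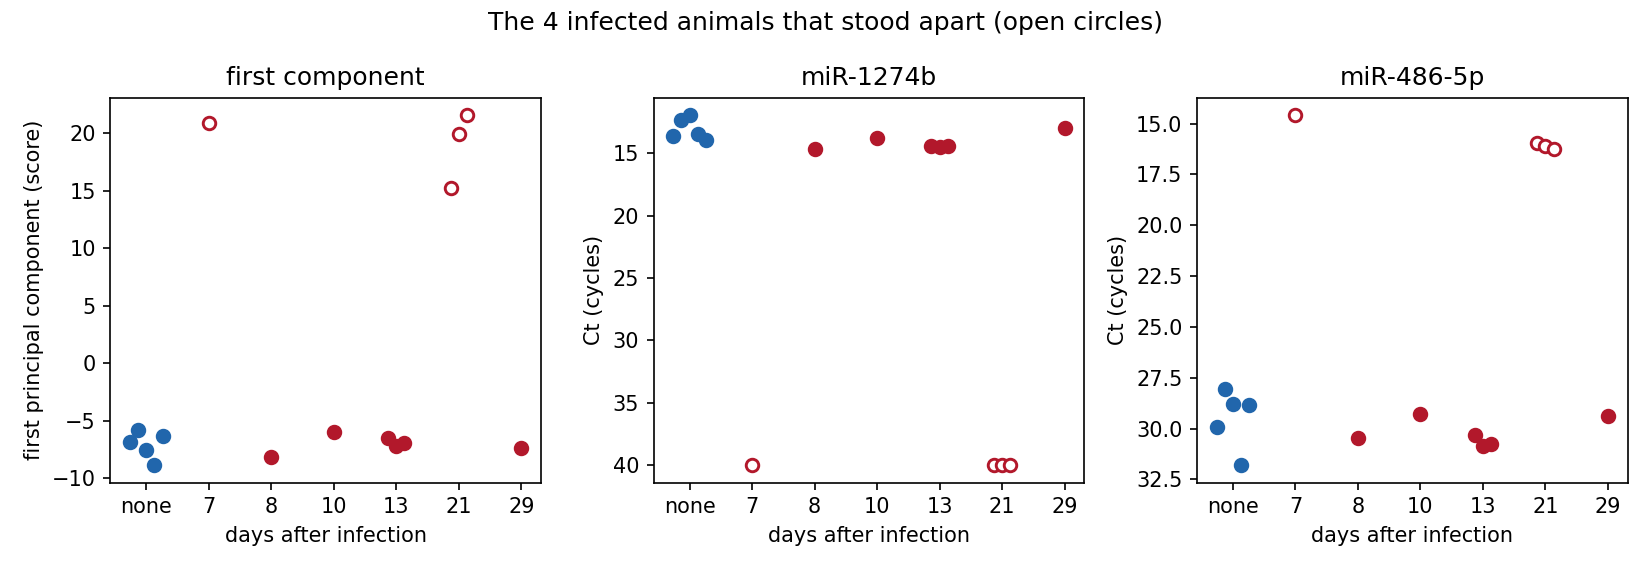
First principal component score (left) and Ct in cycles (axis inverted, so that more RNA is higher) of miR-1274b (middle) and miR-486-5p (right) against days after infection, 1 point per animal, with uninfected animals at none in blue and infected animals in red. Open circles are the 4 infected animals that stood apart, with component scores from 15.3 to 21.5 against -5.79 or lower in the other 11.

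The first comparison asked which miRNAs differ between all infected and uninfected animals. miR-190b rose most firmly, 5.83-fold (95% interval 4.05 to 8.39, log2 difference 2.54, SE 0.246, n = 10 and 5), and every one of the 10 infected animals lay above all 5 uninfected animals. Its level was 0.76 ± 0.457 (SD, n = 10) in infected and -1.79 ± 0.418 (SD, n = 5) in uninfected animals. miR-125b-2-3, the passenger strand of a miR-125b hairpin, rose 5.43-fold (log2 2.44, SE 0.468, 9 of 10 above all uninfected), and miR-200c-5p, the passenger strand of an epithelial hairpin, rose 4.10-fold (log2 2.04, SE 0.486, 9 of 10). miR-223-5p, from the hairpin of the myeloid miR-223, rose 2.84-fold (log2 1.51, SE 0.379, 8 of 10), and miR-222-3p, a regulator of the cell cycle inhibitor p27, rose by 0.59 (SE 0.137, 9 of 10). Adjusted p by limma was 1.96e-05 for miR-190b, 0.0128 for miR-125b-2-3, 0.0325 for miR-200c-5p and miR-222-3p, and 0.0401 for miR-223-5p. miR-190b was always to be named, because the study of these animals reported it, so it is not an independent choice.

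Among the miRNAs that fell, 7 belong to the imprinted DLK1-DIO3 cluster described below, including miR-409-5p, which fell by 1.43 (SE 0.227, 10 of 10 infected below all uninfected, limma adjusted p = 0.00365). miR-425-3p fell by 0.83 (SE 0.157, 10 of 10, adjusted p = 0.0128). miR-27a-3p, an abundant miRNA of the miR-23a cluster, fell by 1.00 (SE 0.219, 9 of 10, adjusted p = 0.0288), and miR-301b fell by 1.42 (SE 0.360, 8 of 10, adjusted p = 0.0401). miR-199a-5p, a mesenchymal miRNA, fell by 0.86 (adjusted p = 0.0335), and miR-324-5p fell by 0.74 (adjusted p = 0.0325). miR-181a-3p, outside the naming rule and named after its value was seen, fell by 0.71 (adjusted p = 0.0325).

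**Figure D2:**
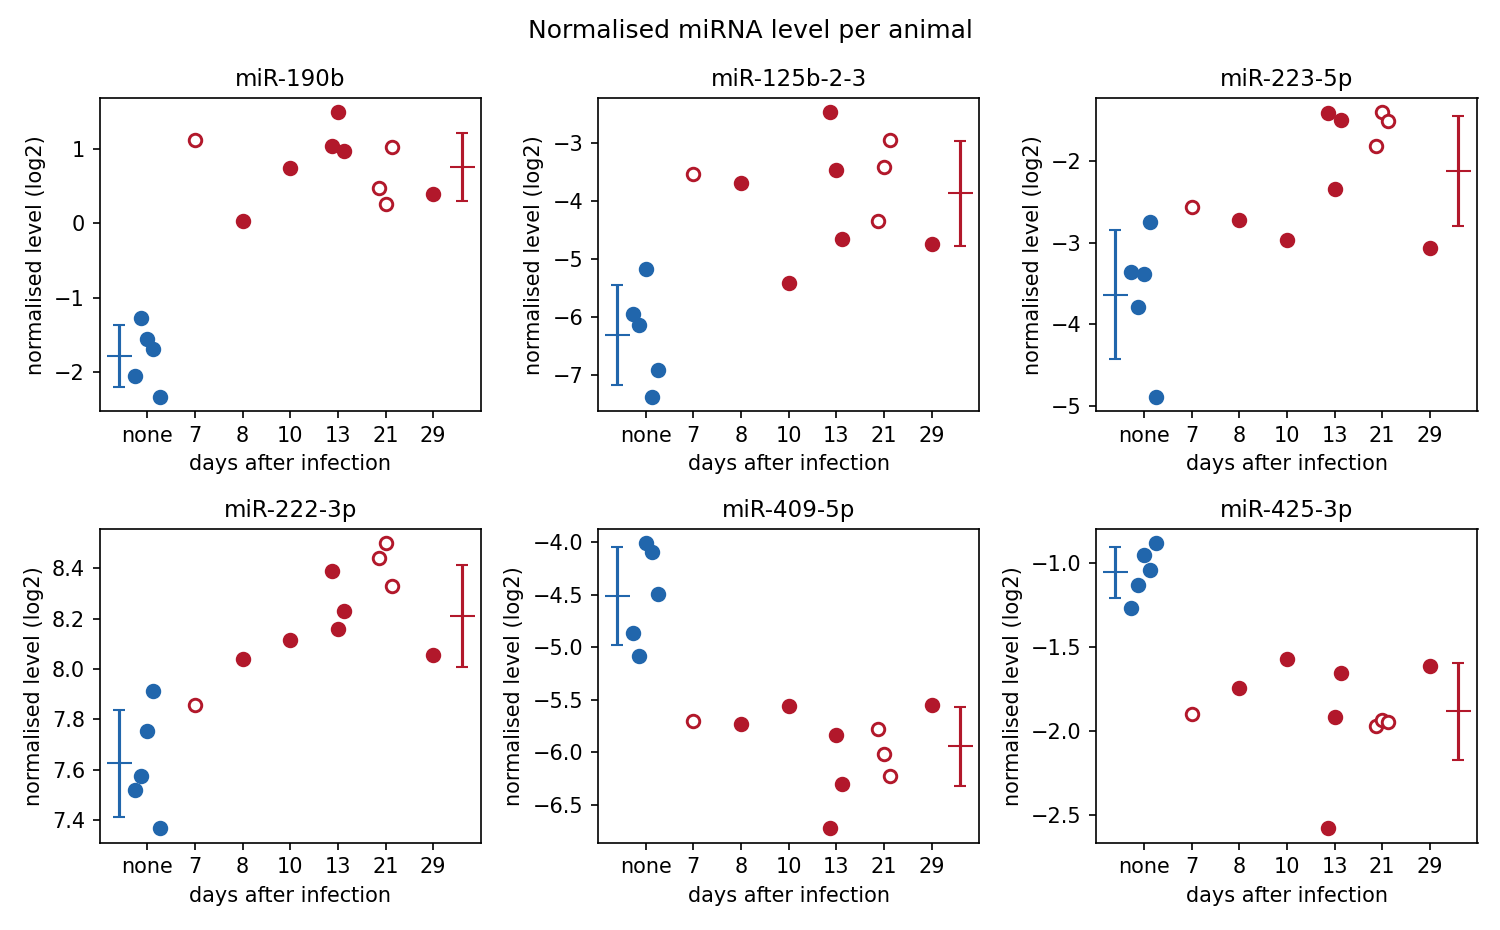
Normalised level (log2) of 6 miRNAs in each animal against days after infection, with uninfected animals at none in blue and infected animals in red. Bars at the sides are group means ± SD (n = 5 and 10), open circles are the 4 infected animals that stood apart, and all 10 infected animals lie above the uninfected ones for miR-190b and below them for miR-409-5p and miR-425-3p.

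Of 441 miRNAs tested with limma, 18 passed an adjusted p of 0.05, 5 higher and 13 lower in infected animals, and 84 had an unadjusted p under 0.05. The median difference over all assays was -0.21, so a miRNA that follows the bulk reads as slightly lower. By card, 1 call was higher and 11 lower on card A (median -0.28), and 4 were higher and 2 lower on card B (median -0.08). With each card scaled by itself the median over all assays was -0.02 and the calls were 5 higher and 1 lower. They were 6 and 5 with the global mean (median -0.08), 9 and 6 after quantile normalisation (median 0.00), and 4 and 15 with control RNAs as the reference (median -0.37), and 7 and 5 with a Ct ceiling of 32 (median -0.06), so the balance of higher and lower calls depends on the scaling and the ceiling. Without the 4 animals that stood apart, 17 miRNAs passed, 5 higher and 12 lower, and 9 of them were among the 18. Of the named miRNAs outside the 18, miR-22-5p (0.71, limma adjusted p = 0.0412) and the DLK1-DIO3 member miR-376c (-0.79, adjusted p = 0.0464) came past the threshold. miR-190b was then 2.55 higher (adjusted p = 4.41e-04), while miR-200c-5p (1.42, adjusted p = 0.0931) and miR-223-5p (1.28, adjusted p = 0.101) did not pass. Nor did miR-301b (-1.28), miR-199a-5p (-0.90), miR-181a-3p (-0.70), miR-324-5p (-0.61) and the DLK1-DIO3 members miR-410 (-0.60), miR-495 (-0.65) and miR-889 (-0.60), with adjusted p from 0.0550 to 0.0934. Leaving out uninfected animal 3 left 4 calls and uninfected animal 2 left 6. Without uninfected 4 or 5, or infected 9, there were 10, and without infected 8 there were 11.

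**Figure D3:**
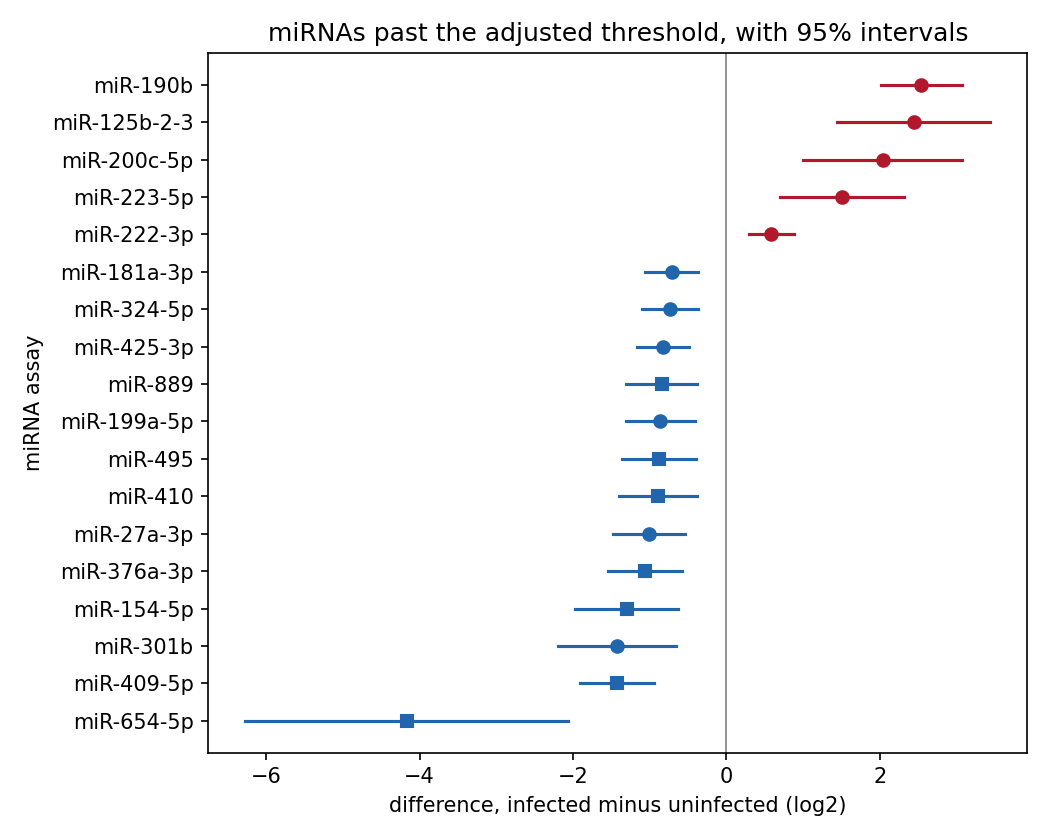
Difference between infected and uninfected animals (log2) for the 18 miRNAs past the adjusted threshold, with 95% intervals from limma (n = 10 and 5), squares for DLK1-DIO3 members and circles for others. The 5 in red were higher and the 13 in blue lower in infected animals, and miR-654-5p is a bound because 6 infected animals were undetermined.

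Several miRNAs lay near the threshold without passing it. miR-22-5p was 0.57 higher (SE 0.162, limma adjusted p = 0.0591, 9 of 10 above all uninfected), and miR-194-3p, an epithelial passenger strand, was 0.98 higher (adjusted p = 0.0824). miR-1226-5p at 2.82 (adjusted p = 0.0591), miR-510 at 3.05 and miR-29b-1-5p at 1.82 (both adjusted p = 0.0824) had wide errors, and miR-510 was detected in 8 of 10 infected and 1 of 5 uninfected animals. The immune miRNAs named in advance had small differences. miR-155-5p, induced in activated lymphocytes and macrophages, differed by 0.12 (95% interval -0.32 to 0.56), miR-146a-5p, a feedback regulator of NF-kB signalling, by 0.19 (-0.29 to 0.66), and miR-223-3p, the abundant myeloid strand, by 0.14 (-0.65 to 0.92). miR-21-5p differed by -0.33 (-0.97 to 0.31) and miR-150-5p, of mature lymphocytes, by -0.31 (-1.07 to 0.44), with limma adjusted p from 0.491 to 0.818 over these 5. Without the 4 animals that stood apart miR-21-5p was at 0.06 and miR-146a-5p at -0.01, so their signs turn. miR-210, induced by hypoxia, differed by -0.74 (-1.37 to -0.12, adjusted p = 0.162). Intervals of this width leave changes of up to about 2-fold undetected for most of these miRNAs.

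The DLK1-DIO3 cluster is an imprinted locus with a large group of miRNAs, which are transcribed from the maternal chromosome. The cluster had the lowest median of the 15 lists. Its fall as a group depends on the test (camera adjusted p = 9.45e-07 at a preset correlation, but adjusted p = 0.273 with an estimated correlation). Of its 47 tested members, 0 rose, 7 fell and 40 did not pass, 44 differed in the negative direction, and 19 fell when adjusted over the list alone. The median member differed by -0.65, against -0.18 for all other assays. Besides miR-409-5p, the members that fell were miR-154-5p (by 1.30, SE 0.312), miR-376a-3p (by 1.06, SE 0.225), miR-410 (by 0.89), miR-495 (by 0.88), miR-889 (by 0.84) and miR-654-5p, with limma adjusted p from 0.0266 to 0.0489. miR-654-5p was 4.17 lower (SE 0.985, limma adjusted p = 0.0325), a bound, since it was undetermined in 6 infected animals (2 to 6 and 10). It was detected in the 4 that stood apart and in all 5 uninfected. The other arm of this hairpin, miR-654-3p, read between -4.28 and -3.56 in these 6 animals and between -3.80 and -2.80 in uninfected ones. A failed miR-654-5p assay is therefore not excluded. The abundant members miR-409-3p at -0.67, miR-127-3p at -0.56, miR-411-5p at -0.49 and miR-376c at -0.43 did not pass (adjusted p from 0.0824 to 0.337). The fry test, which does not compare the list with other assays, gave adjusted p = 0.00120. On card A alone, 33 of 35 members were negative and their median was -0.77 against -0.23 for the other card A assays. On card B 11 of 12 were negative, with a median of -0.50 against -0.03, and 5.46% of random card B lists had as low a median. Computed per animal, the median member relative to the other assays differed by -0.29 between infected and uninfected animals (exact permutation p = 0.344). The difference was -0.25 with each card scaled by itself (exact permutation p = 0.278), and -0.70 without the 4 animals that stood apart (exact permutation p = 0.0152). In the rhesus gene table, 45 of the 47 members have a precursor gene between DLK1 and DIO3.

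Of the 6 epithelial passenger strands, the less abundant arms of hairpins made in gut epithelium, miR-200c-5p rose, 5 did not pass, and 3 rose when adjusted over the list alone. miR-200b-5p was 1.38 higher (adjusted p = 0.0953), miR-200a-5p 0.52 higher, miR-192-3p differed by -0.08 and miR-141-5p by -0.58, so that 4 members were positive and 2 negative. Without the 4 animals that stood apart miR-200b-5p was at 0.65 and miR-200a-5p at 0.11. The median member differed by 0.75 (camera adjusted p = 0.0128, but adjusted p = 0.467 with an estimated correlation and 0.257 with fry). Without those 4 animals the median was 0.38 and the list was not past the threshold (adjusted p = 0.0742). The intestinal epithelium list, which holds the main strands of these hairpins and 3 other miRNAs, had 0 of 9 members past the threshold. Its median was -0.18 (camera adjusted p = 0.804), with miR-192-5p at 0.14, miR-200b-3p at 0.18, miR-200c-3p at -0.11 and miR-375 at -0.20. All 9 of these assays are on card A and 0 of the 6 passenger strands are, so the contrast of strands is also one of cards. With each card scaled by itself the passenger list had camera adjusted p = 0.0165 (0.270 with an estimated correlation).

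**Figure D4:**
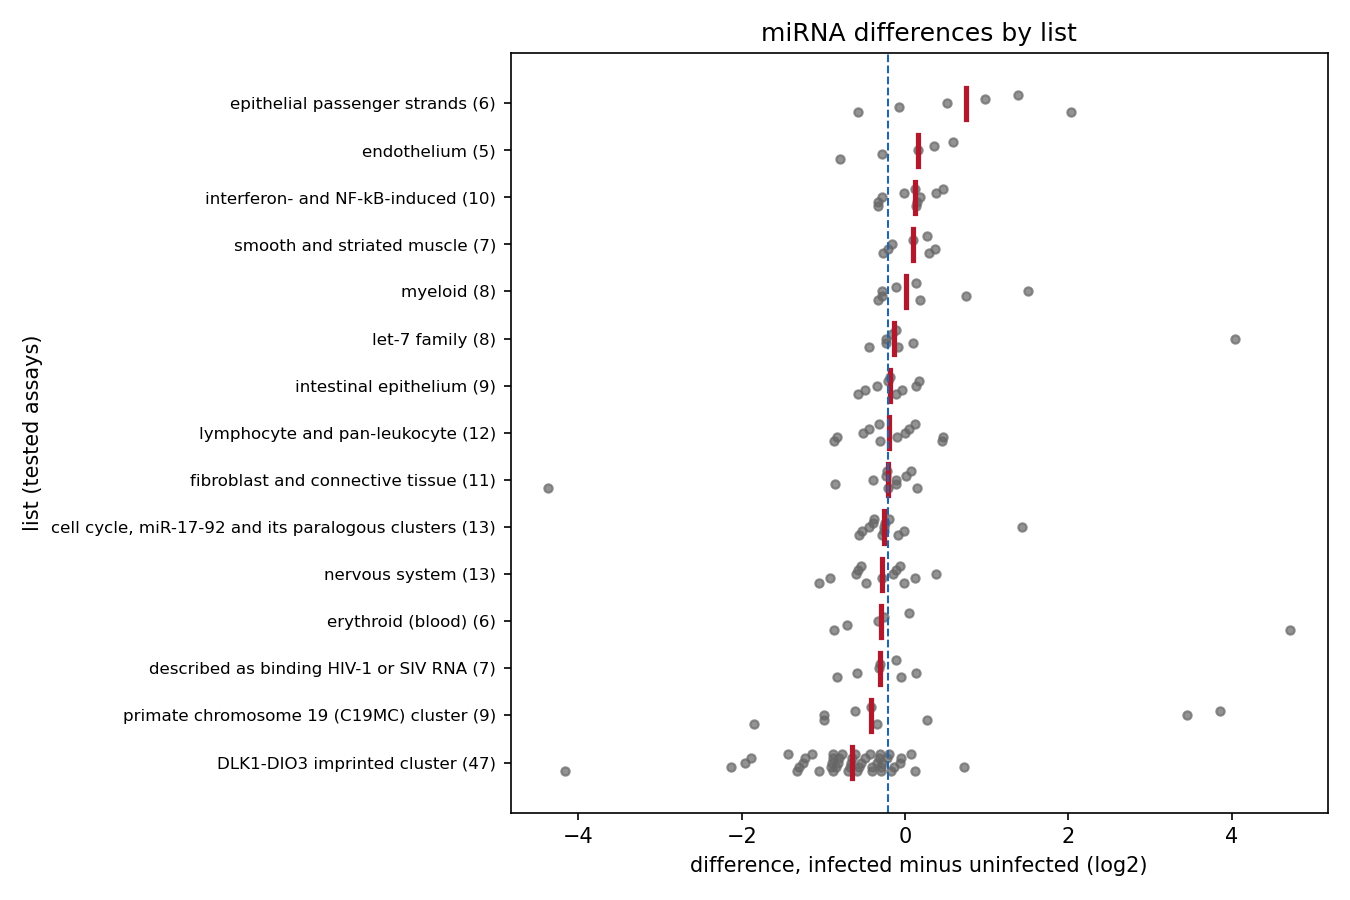
Difference between infected and uninfected animals (log2) for each tested member (grey points) of the 15 lists, with the list's median as a red bar and the median of all 441 assays (-0.21) as a dashed line. The DLK1-DIO3 cluster has the lowest median (-0.65) and the epithelial passenger strands the highest (0.75).

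Lists for other cell types of the colon wall and for immune cells did not pass. Smooth and striated muscle had 0 of 7 members past the threshold (median 0.10, camera adjusted p = 0.416), with miR-145-5p at -0.16, miR-143-3p at -0.26, miR-133a at 0.30 and miR-1 at 0.10. Of 11 fibroblast and connective tissue miRNAs, miR-199a-5p fell and 10 did not pass (median -0.21, adjusted p = 0.804), among them miR-195-5p at 0.08, miR-199a-3p at -0.24, miR-10b-5p at 0.14 and miR-125b-5p at -0.10. Of 5 endothelial miRNAs, miR-222-3p rose and 4 did not pass (median 0.16, adjusted p = 0.416). Its cluster partner miR-221-3p was at -0.79 (adjusted p = 0.0591), and adjusted over the list alone 1 rose and 1 fell. miR-126-3p was at 0.16 and miR-126-5p at 0.35. The nervous system list had 0 of 13 members past the threshold (median -0.29, adjusted p = 0.804), with miR-132-3p at -0.29, miR-218-5p at -0.14, miR-9-5p at -0.01 and miR-7-5p at -0.06. Of 12 lymphocyte and pan-leukocyte miRNAs 0 passed (median -0.20 but camera direction up, adjusted p = 0.935), with miR-29a-3p at -0.31, miR-146b-5p at 0.47 and miR-142-3p at -0.44. Of 8 myeloid miRNAs miR-223-5p rose and 7 did not pass (median 0.02, adjusted p = 0.416). Without the 4 animals that stood apart the medians were 0.13 for fibroblast, -0.07 for nervous system and -0.02 for lymphocyte miRNAs, and the sign turned for miR-192-5p (-0.21), miR-145-5p (0.09), miR-143-3p (0.00), miR-125b-5p (0.32), miR-218-5p (0.06), miR-7-5p (0.47) and miR-142-3p (0.02).

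The remaining lists also stayed short of the threshold. The interferon- and NF-kB-induced list had 0 of 10 members past it (median 0.13, camera adjusted p = 0.416). The 7 miRNAs described as binding HIV-1 or SIV RNA had 0 past it (median -0.31, adjusted p = 0.804), and the 13 of the miR-17-92 family of clusters, which promote cell cycling, had 0 (median -0.26, adjusted p = 0.416), with miR-19b-3p at -0.25, miR-106a-5p at -0.24, miR-17-5p at -0.28 and miR-20a-5p at -0.38. The let-7 family had 0 of 8 (median -0.14, mean 0.36, camera direction up, adjusted p = 0.804), with let-7e-5p at -0.12, let-7g-5p at -0.09, let-7b-5p at 0.10 and let-7d-5p at -0.23, and without the 4 animals that stood apart it was higher (median 0.16, let-7e-5p 0.15, let-7g-5p 0.04, let-7d-5p 0.05, adjusted p = 0.0438, but adjusted p = 0.617 with an estimated correlation). The mean is carried by miR-98, at 4.04, named after its value was seen. The erythroid list had 0 of 6 (median -0.30, mean 0.43, camera direction up, adjusted p = 0.804), with miR-16-5p at 0.05, miR-451a at -0.33, miR-15a-5p at -0.87, miR-144-5p at -0.71 and miR-486-5p, which carries the mean through the 4 animals that stood apart, at 4.72. The miR-15a-5p value rests on infected animal 9, where it was undetermined, and is 0.24 without that animal. miR-16-5p was at -0.16 without the 4 animals. The primate chromosome 19 (C19MC) cluster, placental in most adults, had 9 of 47 members tested and 0 past the threshold (median -0.42, mean 0.26, camera direction down, adjusted p = 0.935), with miR-520c-3p at 3.45, miR-523-3p at 3.86, miR-520d-3p at 0.27 and miR-516a-3p at -1.85. Without the 4 animals that stood apart the 3 positive signs turn, with miR-520c-3p (high in infected 1, 8 and 9) at -0.44, miR-523-3p (high in all 4) at -1.10 and miR-520d-3p at -0.38.

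The next comparisons asked when after infection the differences are present, with each stage set against the same 5 uninfected animals, whose chance values the stages therefore share. At 7 to 10 days (3 animals) miR-190b rose 5.34-fold (log2 2.42, SE 0.303, limma adjusted p = 0.00127), the 1 call of 441, with 45 at an unadjusted p under 0.05 (18 without infected 1, 80 without infected 2, 68 without infected 10). Without infected animal 1, or without all 4 that stood apart, there were 2 calls.

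At 13 days (3 animals) 16 miRNAs passed, 5 higher and 11 lower (7 and 8 with each card scaled by itself). miR-190b rose 7.77-fold (log2 2.96, SE 0.303, limma adjusted p = 1.40e-04), miR-125b-2-3 by 2.77 (SE 0.648), miR-223-5p by 1.89 (SE 0.471), miR-22-5p by 0.93 (SE 0.174) and miR-506-3p by 4.07 (SE 1.02), the last detected in 3 of 5 uninfected animals, with adjusted p from 0.00968 to 0.0446. miR-199b-5p, a mesenchymal miRNA, was undetermined in all 3 animals and in the 10-day animal. It read between 25.07 and 27.48 cycles in each of the other 11. Its difference of -9.10 (SE 1.34, limma adjusted p = 0.00336) is a bound if the assay worked in those animals. The mesenchymal miR-199a-5p read between -2.21 and -1.68 in these 3 animals and between -1.13 and -0.49 in uninfected ones. A loss of miR-199b-5p and a failed assay cannot be told apart. The DLK1-DIO3 members miR-654-5p (-5.77, a bound, undetermined in all 3), miR-337-3p (-1.80, SE 0.422), miR-409-5p (-1.77, SE 0.282) and miR-411-3p (-1.71, SE 0.341) fell, with adjusted p from 0.00495 to 0.0317. None of these 3 animals is among the 4 that stood apart, and without those 4 the count was 33, all 16 included. Without infected 4 it was 6 and without infected 5 it was 9.

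At 21 to 29 days (4 animals) 13 miRNAs passed, 4 higher and 9 lower. The split was 8 and 5 with each card scaled by itself, 4 and 5 with the global mean, 4 and 4 with quantiles and 9 and 72 with control RNAs. miR-190b rose 5.01-fold (log2 2.32, SE 0.278, limma adjusted p = 7.78e-04), miR-125b-2-3 by 2.45 (SE 0.595), miR-126-5p, an endothelial miRNA, by 0.74 (SE 0.176) and miR-222-3p by 0.71 (SE 0.158), with adjusted p from 0.0429 to 0.0458. Among the 9 lower miRNAs past the threshold, the 5 largest falls were in DLK1-DIO3 members. These were miR-369-5p (by 3.25, SE 0.768), miR-154-5p (by 1.80, SE 0.307), miR-409-5p (by 1.38, SE 0.259), miR-654-3p (by 1.33, SE 0.229) and miR-337-5p (by 1.30, SE 0.277), with limma adjusted p from 0.0103 to 0.0458. Of these 4 animals 3 are among those that stood apart, and the count ran from 3 to 133 when single animals were left out. It was 133 without infected 10, 102 without infected 1, and 6 without infected 2 or uninfected 1. It was 7 without infected 4, 5 or 6 or uninfected 5, 5 without uninfected 2 or 3, 4 without infected 7 or 8 or uninfected 4, and 3 without infected 9. Without the 4, the 29-day animal alone remained and 1 miRNA passed, with miR-190b at 2.14 (adjusted p = 0.152). miR-409-5p was then at -1.08, miR-126-5p at 0.41 and miR-369-5p at -0.51 in that animal, none past the threshold. With a term for the 4 animals there were 3 calls. An arm of 1 animal leaves little to call, so the lost calls say little about the 4 animals.

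The stages were also set against each other, which tests whether they differ. At 21 to 29 days against 7 to 10 days, limma called 0 miRNAs, with 20 at an unadjusted p under 0.05 and a smallest adjusted p of 0.861. The smallest unadjusted p belonged to miR-19a-5p (2.94), miR-122-5p (9.73, SE 3.28) and miR-126-5p (0.58) on the higher side and to miR-654-3p (-0.86), miR-342-5p (-1.40) and miR-361-3p (-2.65) on the lower side. miR-190b differed by -0.09 (SE 0.317) between these stages. At 13 days against 7 to 10 days, limma again called 0, with 29 at an unadjusted p under 0.05 and a smallest adjusted p of 0.579. miR-1233 (1.06), miR-30d-5p (0.67), miR-224-5p (0.90), miR-337-3p (-1.59), miR-411-3p (-1.26) and miR-199b-5p (-5.30, with undetermined animals in both stages) had the smallest unadjusted p. Leaving out infected 10 gave 4 calls in the first of these comparisons, and leaving out infected 3 gave 1 in the second. The 20 at an unadjusted p under 0.05 became 86 without infected 1 and 84 without infected 10. The 29 became 11, 66, 46, 16 and 19 without infected 1, 2, 3, 4 and 5. Along the days within the 10 infected animals, limma called 0, with 10 at an unadjusted p under 0.05 and a smallest adjusted p of 0.992. Per 10 days, miR-153 differed by 1.55, miR-19a-5p by 1.62, miR-377-3p by 1.18, miR-342-5p by -1.04, miR-638 by -0.67 and miR-217 by -0.78. Leaving out infected 10 gave 1 call, with 38 at an unadjusted p under 0.05 (19 without infected 1). Without the 4 animals that stood apart limma called 0 in each of these 3 comparisons, with 12, 20 and 18 at an unadjusted p under 0.05 in the order given.

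The authors' deposited table holds their own comparison of all infected with all uninfected animals. It gives a fold change for 435 miRNA assays and a p-value for 412, of which 9 are under 0.05, with 4 folds above 1 and 5 below. The authors' deposited table gives miR-190b a fold of 6.02 (p = 0.0032), miR-222-3p 1.525 (p = 0.0114), miR-425-3p 0.581 (p = 0.0024), miR-223-5p 2.82 and miR-22-5p 1.53. Its other 4 are miR-199a-5p, miR-221-3p, miR-324-5p and miR-361-5p, with folds from 0.574 to 0.657 in the authors' deposited table. All 9 had the same direction in the fit here, and 6 passed its threshold, while miR-22-5p, miR-221-3p and miR-361-5p had limma adjusted p = 0.0591. Across the 340 assays detected in every animal, which are not independent replicates, the 2 sets of fold changes from the same cards had a Spearman correlation of 0.969, and 322 had the same direction. The series' design text names Benjamini-Hochberg correction. miR-223-5p, miR-22-5p, miR-199a-5p, miR-221-3p, miR-324-5p and miR-361-5p have the same p-value in the authors' deposited table, a tie that such adjustment can make. The file headers do not say whether the p-value column is adjusted.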

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

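In this part, the tests for blood, missing primers and days, and those for the DLK1-DIO3 cluster and miR-190b, were chosen after the result was seen, as were the fits without the 4 infected animals that stood apart. A value is listed here when the gap between the most extreme animal and the next one, as a share of the group's whole range, exceeds Dixon's 95% limit. Chance alone does this in about 1 in 20 groups, and 8 of 198 groups did so. miR-425-3p in infected animal 4 was the lowest of 10 (-2.58, next -1.97, gap share 0.607). miR-146a-5p in infected 7 was the highest (9.60, next 8.88, share 0.518), and miR-15a-5p in infected 9 the lowest (-11.97 at the ceiling, next -1.72, share 0.846). let-7g-5p in infected 1 was the lowest (5.00, next 5.62, share 0.619), and the same animal had the most detected assays (445, next 428, share 0.531). Among uninfected animals, miR-19a-5p was highest in animal 2 (-7.94, next -10.68, share 0.726), miR-122-5p lowest in animal 3 (-11.72 at the ceiling, next -6.69, share 0.710), and RNU44 on card B undetermined in animal 5 (Ct 40, next 30.5, share 0.727).

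miR-30d-5p is listed because its difference from uninfected animals was -0.37 at 7 to 10 days and 0.30 at 13 days. The difference of 0.67 between these was tested directly with limma and had an adjusted p of 0.579. The plant miRNA assay, a negative control, is listed because it gave a signal, with a lowest Ct of 30.7 on card A in infected animal 3 (undetermined in all uninfected animals) and of 30.8 on card B in infected animals (33.6 in uninfected ones), where 6 animals had a Ct under 35.

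The pattern weighed first is that 4 infected animals (1, 7, 8 and 9) stood apart. Blood in the tissue is argued against, because the red-cell miRNAs miR-451a (1.46), miR-144-5p (-0.42) and miR-486-3p had a median shift of 1.28 from the other 6 infected animals, while miR-486-5p shifted by 13.71. The median is the miR-486-3p value. That assay was detected in 3 of 10 infected animals, all among the 4, so its shift is limited by the Ct ceiling. The argument rests on miR-451a and miR-144-5p. miR-144-3p was detected in 1 of 10 infected animals and was not tested. Days since infection do not order the set, which holds the animals of 7 and 21 days but not those of 8, 10, 13 and 29 days. On the first component the 7-day animal lay 26.9 from the nearer of the 8- and 10-day animals, and at most 5.65 from any 21-day animal. The set was picked on this component, so these distances are no separate test, and the 7-day value rests on 1 animal. Primers missing for a block of assays are a candidate explanation for the 17 assays silent in them alone, since 94.1% of these lay in the last 96 wells of card B (6.63% of all assays seen in the other 11), where 6 of 24 were seen in all 4. They are not one for the whole pattern, because the 4 also lay apart on card A scaled by itself (gap 19.3 on its first component, range within the 4 1.21). The component on which the set was picked included these 225 card A assays, so the gap is no separate test. It shows only that assays outside the block differed as well. Differences between card or reagent lots for single assays stay open, because the 2 arms of 92 hairpins shifted apart by a median of 0.659, at the edge of random pairs (0.660 to 1.09), with a bootstrap spread of 0.539 to 0.951, and no other biological explanation was tested.

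The pattern weighed second is that DLK1-DIO3 members were lower, a group call that is lost with an estimated correlation (adjusted p = 0.273, and 0.501 without the 4 animals). The 4 animals are argued against as its whole cause, because without them the members lay -0.53 from the other assays. Joint scaling of the 2 cards is argued against only for the gap within card A. That gap was -0.54, and the members' median of -0.77 lay below that of random card A lists (-0.40 to -0.14). On card B the gap of -0.47 was not outside chance (5.46% of random lists as low). With each card scaled by itself the per-animal difference was -0.25 (exact permutation p = 0.278). The list's camera adjusted p was then 0.270 with an estimated correlation. Lower calls among all assays went from 13 to 1 with that scaling, so calls of single members depend on it. Less connective tissue or muscle is argued against by the cluster minus these 2 lists per animal (difference -0.53 over members detected in every animal, exact permutation p = 0.0296, and -0.42 over all tested members, p = 0.0390). Unrelated differences of single assays are argued against only where assays vary independently, since 0% of random lists of equal size and cards had as low a median. The cluster was taken up because its median was the lowest of the lists, so this is not separate support. Random lists also leave out the correlation between members, estimated at 0.118. The cluster may be lower in infected colon as a hypothesis found in these data, with the limits that its per-animal value over all 15 had an exact p of 0.344 and that infected and uninfected cards may have been run apart, which the labels do not give.

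The last pattern weighed is that miR-190b was higher. Cross-amplification of miR-190a, chosen after its value was seen, is argued against, because that miRNA differed by -0.87 (95% interval -1.89 to 0.15). The 4 animals are argued against, because without them the difference was 2.55 (1.93 to 3.16). A run difference of this assay between infected and uninfected cards cannot be told apart from infection, because the labels give no run. Between the 4 animals and the other 6 infected ones, 14 of 340 assays differed by as much. miR-190b is not among these 14, with a difference of -0.06, which does not bear on a difference between infected and uninfected cards.

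Other splits of the same animals were fitted for each comparison of groups, each count below being miRNAs past the threshold. For all infected against uninfected animals no other drawn split gave as many (18, highest of the other drawn splits 2, with 1 of 100 splits as large). This does not exclude chance, because the real split keeps the 4 animals that stood apart in 1 arm. Many other splits mix them across both arms. Among drawn splits with none of the 4 in the smaller arm the highest count was 1, but the number of such splits was not recorded. For 13 days against uninfected chance is argued against (16, highest other 1, with 1 of 56). For 21 to 29 days against uninfected no other drawn split gave as many (13, highest other 5, with 1 of 100). At 21 to 29 days this is no evidence for the stage itself, because 3 of its 4 animals stood apart and the other splits mix them across both arms, and with a term for the set 3 miRNAs were called. For 7 to 10 days against uninfected chance cannot be excluded for the count (1, highest other 15, with 6 of 56). The highest split there set infected 2 and 3 with uninfected 1, 2 and 3 against the rest. For 21 to 29 against 7 to 10 days the real count is 0, so each of the 35 splits is as large by construction and nothing follows about chance (highest other 172). That split of 172 set infected 1, 7, 8 and 9 against infected 2, 3 and 10, which points to a structure of the samples. The same holds for 13 against 7 to 10 days (0, highest other 0), where 10 splits would also be too few. For the number of lists past the threshold chance cannot be excluded (2, highest other 7, with 45 of 100).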

How the results depend on the processing

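In this part the fits without the 4 infected animals that stood apart, with a term for them, and without them with each card scaled by itself were chosen after seeing the data. Of 3319 values of named miRNAs under the alternatives, 2948 were on the same side of the threshold (125 of them with the other sign and neither value past it), 342 were no longer past it, 28 came past it and 1 reversed, and of the list values 440 were on the same side, 7 lost and 2 gained. miR-190b was past the threshold in 15 of 16 settings (2.36 to 2.92) and in 15 of 15 fits that left out 1 animal, while miR-410 was so in 4 of 16 and 4 of 15. For all infected against uninfected animals (18) the count was 11 with the global mean, 6 with each card by itself, 1 on raw Ct and 9 without the 4 animals with each card by itself. For 7 to 10 days (1) it was 2 with undetermined values missing, 0 on raw Ct and 2 without the 4. For 13 days (16) it was 2 on raw Ct and 33 without the 4. For 21 to 29 days (13) it was 33 with undetermined values missing, 43 with assays detected in all 15 animals, 6 with those detected in at least 1, 81 with control RNAs, 8 with quantiles, 1 on raw Ct, 1 without the 4 (which leaves 1 animal, assumed to vary like the others) and 3 with a term for them. For 21 to 29 against 7 to 10 days (0) it was 1 with undetermined values missing, and for the slope (0) 1 with these missing and 1 with control RNAs. Lists past the threshold (2) numbered 1 on raw Ct, 1 with fry and 0 with an estimated correlation, and camera was not run with missing values. miR-7-5p reversed without the 4 with each card by itself, 0.71 against -0.06 (adjusted p = 0.0147, range over its alternatives 0.0147 to 0.976). For these changes the cause was not tested.

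Leaving out each animal in turn gave 4 to 25 for all infected (4 without uninfected 3, 6 without uninfected 2, 10 without uninfected 4 or 5 or infected 9, 11 without infected 8), 1 to 2 at 7 to 10 days (2 without infected 1), 6 to 18 at 13 days (6 without infected 4, 9 without infected 5) and 3 to 133 at 21 to 29 days (133 without infected 10, 102 without 1, 7 without 4, 5 or 6, 6 without 2, 4 without 7 or 8, 3 without 9; without uninfected animals 1 to 5 in turn 6, 5, 5, 4 and 7). It gave 0 to 4 for 21 to 29 against 7 to 10 days (4 without infected 10), 0 to 1 for 13 against 7 to 10 days (1 without infected 3), 0 to 1 for the slope (1 without infected 10), 1 to 2 for lists (1 without uninfected 3) and 0 to 2 for control RNAs (2 without uninfected 3, adjusted p = 0.0240).

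With the label number as a block for numbers 1 to 5, limma called 0 for all infected against uninfected animals. The numbers do not pair the animals, since infected and uninfected are different macaques and 2 of 5 infected animals correlated best with the uninfected animal of their own number (correlations from -0.06 to 0.19). The cause of the lost calls was not tested. The number of animals limits what can be called, with 49.8% of 1 log2 unit changes recovered in simulated data with independent errors. Background near Ct 30.7 limits assays of low level.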

Other observations

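The test in this part was planned before its result was seen, and miR-122-5p was named by the rule while its values per animal were looked at afterwards. miR-122-5p, a miRNA of liver, was at 1.79, 3.43 and 2.59 in the 3 animals of 21 days (infected 7, 8 and 9), and at -4.53 or lower in the other 12. Infected 1, which stood apart together with these 3, was undetermined for it. In raw Ct the 3 animals read 21.4, 19.5 and 20.4 cycles.

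The hypothesis that infection moves the ratio of passenger to guide strand across hairpins came from miR-125b-2-3, miR-200c-5p, miR-223-5p and the epithelial passenger strands. The test took 92 hairpins with both arms detected in every animal, with the arm of higher mean level as the guide. These include the hairpins that gave the hypothesis (miR-125b at 2.54, miR-200c at 2.14 and miR-223 at 1.37), so the test is not independent of it. The mean change of the ratio was 0.21 (59 up, exact permutation p = 0.0866) and 0.13 with each card by itself (54 up, p = 0.0749). It was 0.08 without the 4 infected animals that stood apart (51 up, p = 0.361). With a largest p of 0.361, a shift common to hairpins was not shown in all 3 settings, and a small one is not excluded.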
